A study of Mus musculus with 18 samples.

How the data were processed

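RNA from whole lumbar DRG of 18 male C57BL/KaLwRijHsd mice was compared between 9 mice inoculated in the femur with 5TGM1-GFP myeloma cells (MM) and 9 given vehicle (SHAM), all sampled on post-surgical day 24. Each library was taken as 1 mouse, as the series design states. The labels name no batch, day or pairing, so the replicate number was left out of the model. Total RNA was sequenced on DNBSEQ instruments by a service provider.

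The authors quantified each library with Salmon 1.5.2 against transcripts of the GRCm39 build, per the labels; the index and options are not stated. The deposited quantification files hold, per transcript, an estimated count of reads that is not a whole number and that the authors did not scale. The deposited TPM values in the same files were scaled by Salmon to transcripts per a fixed total, and the effective transcript lengths beside them were estimated per library. The deposited table of all samples holds a normalized signal per gene, which the authors made with DESeq2 (no version stated). How DESeq2 scaled the estimated counts was checked only by the comparison with scaled sums below.

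Estimated counts were summed per gene and rounded. Links between transcripts and genes came from GENCODE M21, which annotates GRCm38, by Ensembl transcript number without its version. Because that build is older than the authors' build, no genome positions are given and identifiers serve as names only. Of 137562 transcripts in the files, 3620 had no gene in this annotation and held between 0.85% and 1.339% of reads per library; they were tested apart. The sums gave 48529 genes and between 19218249 and 21771206 estimated reads per library. As a check of the links, 78.27% of values of 8978 well-measured genes in the deposited table lay within 5% of the scaled sums. The deposited table listed 17787 genes, of which 17750 had a gene in the annotation.

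Genes were kept by edgeR's filterByExpr (15774 genes), scaled by TMM and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with group as the only term; the common biological coefficient of variation was 0.258. Benjamini-Hochberg adjusted p under 0.05 counted as passing. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. On simulated counts for the same number and sizes of libraries, 42% of genes with a 1.25-fold change, 84% with a 1.5-fold change, 96% with a 2-fold change and 98% with a 4-fold change were recovered, with 6 false among 166 calls. The simulation took the spread of SHAM libraries alone, drew genes independently and changed only genes at a SHAM mean of at least 1 CPM. The distance of MM5, MM8 and MM9 from the other libraries was not simulated, so real recovery may be lower. The number of reads per library sets the precision of low values: where a count is 0, 3 counts is the limit given. Shares in single libraries carry 95% Wilson intervals, which cover counting error only.

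Before the data were examined, 36 gene lists were fixed for cell types and programmes of the ganglion and its surroundings. A list with under 5 measured members was not tested, which left 35. Some genes stand in more than 1 list: Pvalb (A-fibre neuron and skeletal muscle), Hmgcs1 (satellite glia and cholesterol synthesis), Per1 (glucocorticoid response and circadian clock), Plin4 (adipocyte and glucocorticoid response) and Lcn2 (neutrophil, complement and glucocorticoid response). Lists were tested against all other genes with camera, at a preset correlation of 0.01 between genes and at an estimated correlation. The rotation test fry asked whether the members of a list moved 1 way on balance, without comparison with other genes; both tests came from limma 3.58.1 and edgeR. The level of a list is the mean log2 CPM over its measured members in a library. Levels and the summed CPM of immunoglobulin constant-region genes were compared with a 2-sided exact permutation test over all assignments of 18 libraries to 9 and 9, and Benjamini-Hochberg correction over lists. Without some SHAM libraries the groups were unequal, and assignments with high libraries in the smaller group can give a large difference too. A call lost there need not mean that the result rests on the libraries left out. Exact tests, intervals and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

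The rule for named genes was fixed before the data were examined. Among genes past the threshold with a mean of at least 1 CPM, a symbol that is not a predicted model and at least 8 of 9 MM libraries on the side of the change relative to the SHAM median, it took the 8 largest rises, the 8 largest falls and the 4 lowest p in each direction. It added up to 2 members per list and direction with the lowest p, and always Samsn1, Xist, Ddx3y, Atf3, Calca and Ighg2b. Some results that the rule would name are not reported here. Acta1, Aif1, C1qa, C1qb, C1qc, Ms4a7 and the genes named only in the closing section were chosen after their values were seen, as was the range relative to Ighg2b.

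Alternatives fixed beforehand were RLE scaling and scaling by total counts, no filter and a mean of at least 1 CPM, an offset for transcript length, limma-voom with and without library weights, DESeq2 1.42.0, and limma on the logarithm of the deposited normalized values with pseudocounts of 1 and 0.1 and with and without a filter at a mean of 10. Further ones were surrogate variables (sva 3.50.0; 3 variables), the mean level of 3 neuron lists as a covariate, a block for replicate number, list levels as medians, and leaving out each library in turn. Chosen after seeing the data were fits without MM5, MM8 and MM9, fits without SHAM7 and SHAM8, and the skeletal muscle level and the immunoglobulin level as covariates. For the counts of genes and of camera lists, 100 of the 24310 splits of the libraries into 9 and 9 were drawn with a fixed seed, the real one included.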

Results

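Dorsal root ganglia (DRG) hold the cell bodies of the sensory neurons that supply limb and trunk, together with glia, vessels and resident immune cells. RNA was sequenced from whole lumbar DRG of 18 male mice of the strain C57BL/KaLwRijHsd, taken from the inoculated side on post-surgical day 24. In the MM group, 9 mice had received 5TGM1-GFP cells, a mouse myeloma (malignant plasma cell) line, in the femur. In the SHAM group, 9 mice had received vehicle. The deposited quantifications held between 19218249 and 21771206 estimated reads per library.

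The strain and sex labels were checked on 3 genes. Samsn1 (ENSMUSG00000022876), a gene deleted in KaLwRij mice, had 1 read over all 18 libraries, and no library exceeded 0.05 CPM (read counts scaled to a common library size). In these libraries 3 counts corresponded to between 0.14 and 0.16 CPM. Xist (ENSMUSG00000086503), transcribed from the inactive X chromosome of females, stayed at or under 0.505 CPM. Ddx3y (ENSMUSG00000069045), a Y-linked gene, was at 37.3 ± 8.07 CPM in MM and 38.9 ± 3.97 CPM in SHAM (SD, n = 9 each); edgeR gave adjusted p = 0.767.

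The comparison of MM with SHAM asks how the ganglia that supply the inoculated limb differed between myeloma-inoculated and vehicle-treated mice. Of 16 measured markers of B, plasma and myeloma cells 10 rose and 2 fell, and of 18 cell cycle genes 15 rose. Ighg2b (ENSMUSG00000076613), the constant region of the IgG2b heavy chain, was at 1156 ± 1495 CPM in MM and 4.20 ± 6.52 CPM in SHAM (SD, n = 9 each; log2 fold change 8.10 ± 1.27 SE). Of 25 interferon response genes 16 rose, and their level lay above the SHAM median in every MM library, at 4.21 ± 0.59 in MM and 3.33 ± 0.29 in SHAM (mean log2 CPM over members; SD, n = 9 each; exact permutation p = 0.000576). Of 7 red blood cell genes 6 fell, with Hba-a1 (ENSMUSG00000069919), an alpha globin, at 30.3 ± 15.1 CPM in MM and 213 ± 213 CPM in SHAM (SD, n = 9 each). Among 16 markers of non-peptidergic and itch neurons 2 fell, and the nociceptor receptor gene Mrgprd (ENSMUSG00000051207) was at 113 ± 14.0 CPM in MM and 136 ± 8.84 CPM in SHAM (SD, n = 9 each). In all, 433 genes rose and 38 fell among 15774 tested. The genes named below as risen or fallen had an edgeR adjusted p between 0.00681 and 0.0490, and at least 8 of 9 MM libraries lay on that side of the SHAM median.

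Of 16 measured markers of B, plasma and myeloma cells, 10 rose, 2 fell and 4 did not pass the test; adjusted over the list alone, 12 rose and 3 fell. The list level was 2.88 ± 1.44 in MM and 0.86 ± 0.41 in SHAM (SD, n = 9 each; exact permutation p = 0.000535, adjusted p = 0.00576), and 8 of 9 MM libraries lay above the SHAM median. It was highest in MM9 (5.03), MM5 (4.59) and MM8 (4.10), against at most 2.66 in the other MM libraries. The set test camera compared each list with all other genes. It gave this list adjusted p = 2.72e-08 with a preset correlation between genes, and adjusted p = 0.308 with an estimated correlation. Igkc (ENSMUSG00000076609), the kappa light chain constant region, was at 963 ± 1194 CPM in MM and 5.96 ± 5.22 CPM in SHAM (SD, n = 9 each). Among variable-region genes, Ighv1-54 (ENSMUSG00000094787) was at 259 ± 354 CPM in MM and 0.886 ± 1.59 CPM in SHAM (SD, n = 9 each). Igkv10-96 (ENSMUSG00000094420) was at 342 ± 457 CPM in MM and 1.15 ± 2.15 CPM in SHAM (SD, n = 9 each). Immunoglobulin genes are related in sequence, so their estimates share ambiguous reads. Irf4 (ENSMUSG00000021356), a transcription factor of plasma cells, was at 33.2 ± 43.6 CPM in MM and 0.849 ± 0.393 CPM in SHAM (SD, n = 9 each). Pou2af1 (ENSMUSG00000032053), a B-lineage coactivator, was at 32.7 ± 41.4 CPM in MM and 0.789 ± 0.444 CPM in SHAM (SD, n = 9 each). Outside the list, Il5ra (ENSMUSG00000005364), an interleukin-5 receptor chain, rose by 5.98 ± 0.89 and Lax1 (ENSMUSG00000051998), a lymphocyte membrane adaptor, by 5.60 ± 0.84 (log2 fold change ± SE, n = 9 each).

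Of the members of that list that fell, Cd79a (ENSMUSG00000003379), a B cell receptor chain, was at 2.17 ± 0.633 CPM in MM and 3.94 ± 1.80 CPM in SHAM (SD, n = 9 each). Its edgeR adjusted p was 0.0490, and with 1 library left out the call was lost in 15 of 18 fits.

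The summed CPM of immunoglobulin constant-region genes was 2181.8 ± 2712.4 in MM and 63.9 ± 25 in SHAM (SD, n = 9 each; 2-sided exact permutation p = 0.000165, where the smallest p that the assignments can give is 4.11e-05). It ranged from 68.0 to 7835.3 over MM libraries, and 8 of the 9 exceeded the highest SHAM value of 121.8. The difference in this immunoglobulin transcript share was 2117.9 CPM with all libraries, 1411.2 CPM without MM9 and 447.5 CPM without MM5, MM8 and MM9. Without SHAM7 and SHAM8 it was 2125.9 CPM and did not pass (exact permutation p = 0.0517). Groups were then unequal in size, and assignments with the highest libraries in the smaller group also gave a large difference. That p therefore does not show that the difference rests on SHAM7 and SHAM8. Library MM2 had 11.7 CPM of Ighg2b, below SHAM5 with 14.8 CPM and SHAM9 with 16.4 CPM; the other SHAM libraries had at most 2.83 CPM. Ighv1-54 held a median 99.1% of heavy chain variable reads over MM libraries. In MM2 it held 88.7% of 62 reads (95% Wilson interval 78.5% to 94.4%). Its share was 81.0% of 84 reads in SHAM5 (71.3% to 87.9%) and 89.9% of 89 reads in SHAM9 (81.9% to 94.6%). The next highest SHAM library was SHAM1, with 40% of 20 reads (21.9% to 61.3%). These intervals cover counting error only, as reads without molecular identifiers are not independent molecules. To see which genes followed Ighg2b, the CPM above the SHAM mean was divided by Ighg2b in each of the 8 MM libraries with more Ighg2b than any SHAM library. The highest of these ratios over the lowest was taken as the range of a gene, and Ighg2b itself ranged 42.0-fold there. Where a library lay at or under the SHAM mean, the range was not defined and was ranked as the largest. The median range was 7.53-fold over 432 rising genes, 4.17-fold over 9 rising members of the B, plasma and myeloma cell list and 2.96-fold over 15 rising cell cycle genes.

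**Figure D1:**
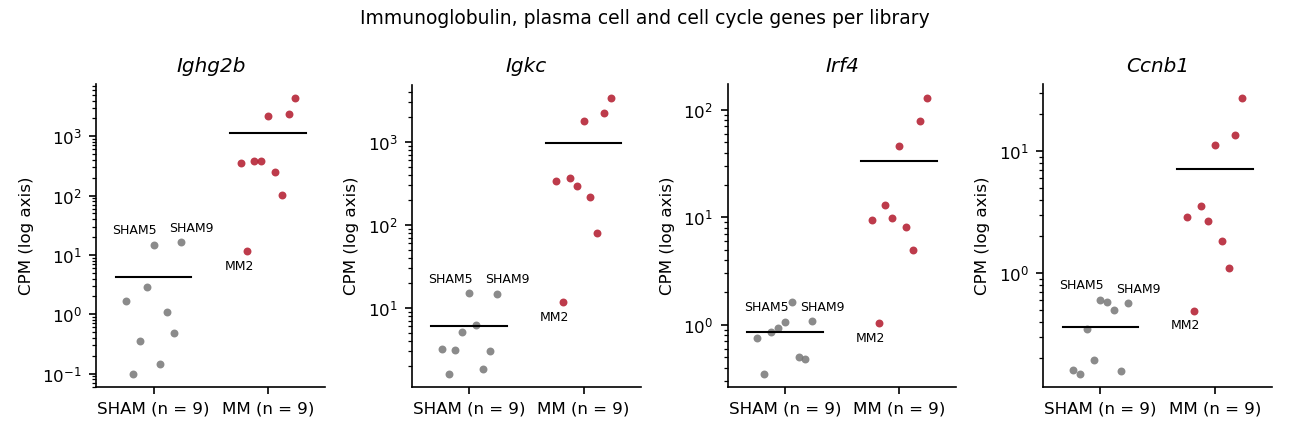
CPM of Ighg2b, Igkc, Irf4 and Ccnb1 in each library on a log axis, with MM and SHAM side by side, 1 point per library in order of its number and a line at each group's mean (n = 9 each). Ighg2b lay between 104 and 4370 CPM in 8 MM libraries, while MM2 (11.7 CPM), SHAM5 (14.8 CPM) and SHAM9 (16.4 CPM) are marked.

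Cell cycle genes rose together: 15 of 18 measured members rose, 0 fell and 3 did not pass, and adjusted over the list alone all 18 rose. Their level was 2.55 ± 1.36 in MM and 0.83 ± 0.37 in SHAM (SD, n = 9 each; exact permutation p = 0.000658, adjusted p = 0.00576), with 9 of 9 MM libraries above the SHAM median. It was highest in MM9 (4.85), MM8 (3.95) and MM5 (3.84), against at most 2.32 in the other MM libraries. By camera the list had adjusted p = 2.93e-19, and adjusted p = 0.308 with an estimated correlation. The mitotic cyclin gene Ccnb1 (ENSMUSG00000041431) was at 7.15 ± 8.77 CPM in MM and 0.363 ± 0.200 CPM in SHAM (SD, n = 9 each). Its kinase partner Cdk1 (ENSMUSG00000019942) was at 6.48 ± 7.39 CPM in MM and 0.659 ± 0.325 CPM in SHAM (SD, n = 9 each). Genes for cytosolic ribosomal proteins had a level of 7.35 ± 0.53 in MM and 6.81 ± 0.12 in SHAM (SD, n = 9 each; exact permutation p = 0.000823, adjusted p = 0.00576), again with 9 of 9 MM libraries above the SHAM median. The exact test of this level no longer passed without MM5, MM8 and MM9 (adjusted p = 0.0517), without SHAM7 and SHAM8 (adjusted p = 0.0906) or with a replicate block (adjusted p = 0.082). In MM9, MM5 and MM8 it stood at 8.26, 8.09 and 7.72, against at most 7.17 in the other MM libraries, and the median range relative to Ighg2b was 6.25-fold over 5 rising members. Of its 28 members 5 rose and 23 did not pass, and adjusted over the list alone all 28 rose. Rps27a (ENSMUSG00000020460) rose by 0.95 ± 0.24 and Rpl18 (ENSMUSG00000059070) by 0.94 ± 0.23 (log2 fold change ± SE, n = 9 each). Camera gave this list adjusted p = 2.8e-20, and adjusted p = 0.308 with an estimated correlation. For the unfolded protein response, a stress programme of the endoplasmic reticulum, 1 of 16 members rose and 8 rose adjusted over the list alone. That member, the disulfide isomerase gene Pdia4 (ENSMUSG00000025823), was at 88.7 ± 63.1 CPM in MM and 40.6 ± 5.10 CPM in SHAM (SD, n = 9 each). The list passed with camera (adjusted p = 2.26e-05; adjusted p = 0.361 with an estimated correlation). Its level did not (exact permutation p = 0.0215, adjusted p = 0.0753), except without MM3, MM6 or MM7 (adjusted p = 0.0432, 0.0432 and 0.0429). That level was 6.45 in MM9, 6.20 in MM8 and 6.10 in MM5, against at most 5.52 in the other MM libraries, and camera gave adjusted p = 0.0181 without these 3.

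Of 25 measured interferon response genes, 16 rose, 0 fell and 9 did not pass; adjusted over the list alone, 21 rose. All 25 had positive fold changes. The list was called by camera (adjusted p = 6.23e-28; adjusted p = 0.205 with an estimated correlation) and by the rotation test fry, which asks whether members move 1 way on balance (adjusted p = 0.0214). Ifi44 (ENSMUSG00000028037) was at 7.10 ± 3.55 CPM in MM and 1.97 ± 0.608 CPM in SHAM, without overlap between the groups, and Irf7 (ENSMUSG00000025498), a transcription factor that amplifies type I interferon, at 29.9 ± 21.7 CPM in MM and 6.75 ± 2.17 CPM in SHAM (SD, n = 9 each). The level of this list was highest in MM5 (5.32), MM9 (4.83) and MM8 (4.53), which were also the libraries with the most Ighg2b, while the median range relative to Ighg2b was 22.2-fold over 16 rising members. Of these members Stat2 had no defined range. The highest ratio of Ifi44 and of Irf7 was in MM7, with the least Ighg2b of the 8 libraries (104 CPM), and ranges without MM7 were not taken. With a replicate block the exact test of the interferon response level gave adjusted p = 0.0684.

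Antigen presentation genes had 6 members that rose of 16 measured and 10 that did not pass, and 11 rose adjusted over the list alone. Their level was 5.25 ± 0.66 in MM and 4.51 ± 0.30 in SHAM (SD, n = 9 each; exact permutation p = 0.00292, adjusted p = 0.017), with 9 of 9 MM libraries above the SHAM median. Without SHAM1, SHAM5 or SHAM8 (adjusted p = 0.0549, 0.0516 and 0.0542) the level no longer passed the exact test. The same held without MM5, MM8 and MM9 (exact adjusted p = 0.168), without SHAM7 and SHAM8 (adjusted p = 0.13), with a replicate block (adjusted p = 0.137) and with medians over members (adjusted p = 0.0873). The level was highest in MM5 (6.45), MM9 (6.10) and MM8 (5.72), against at most 5.04 in the other MM libraries, and the median range relative to Ighg2b was 3.05-fold over the 6 members that rose. For this list camera gave adjusted p = 5e-10, and adjusted p = 0.308 with an estimated correlation. H2-K1 (ENSMUSG00000061232), a class I heavy chain with close paralogs, was at 300.3 ± 290.0 CPM in MM and 61.5 ± 11.5 CPM in SHAM (SD, n = 9 each). The immunoproteasome gene Psmb9 (ENSMUSG00000096727) was at 9.62 ± 7.97 CPM in MM and 2.92 ± 0.802 CPM in SHAM (SD, n = 9 each).

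Macrophage markers rose in 7 of 20 measured members, with 13 not passing and 15 rising adjusted over the list alone. Their level was 3.15 ± 0.85 in MM and 2.24 ± 0.39 in SHAM (SD, n = 9 each; exact permutation p = 0.0058, adjusted p = 0.029), with 9 of 9 MM libraries above the SHAM median. That level no longer passed the exact test without MM5, SHAM1, SHAM2, SHAM3, SHAM5, SHAM7, SHAM8 or SHAM9 (adjusted p = 0.0502, 0.0718, 0.0529, 0.0531, 0.0596, 0.0619, 0.0675 and 0.0654). Nor did it without MM5, MM8 and MM9 (exact adjusted p = 0.229), without SHAM7 and SHAM8 (adjusted p = 0.134), with a replicate block (adjusted p = 0.164) or with medians over members (adjusted p = 0.0873). The level was highest in MM5 (4.74), MM9 (4.20) and MM8 (3.65), against at most 2.84 in the other MM libraries. The camera test gave adjusted p = 6.35e-11, and adjusted p = 0.308 with an estimated correlation. The lysosomal genes Cd68 and Ctss had the lowest p of the list, and their range relative to Ighg2b was 2.22-fold and 3.08-fold. For the other 5 that rose, Aif1, C1qa, C1qb, C1qc and Ms4a7, it lay between 13.5-fold and 34.8-fold. The 13.5-fold range of Aif1 leaned on MM7, where it stood at 2.2 CPM beside 104 CPM of Ighg2b. Cd68 (ENSMUSG00000018774) was at 26.7 ± 29.9 CPM in MM and 3.07 ± 1.22 CPM in SHAM (SD, n = 9 each). Ctss (ENSMUSG00000038642) was at 58.6 ± 62.0 CPM in MM and 9.00 ± 3.13 CPM in SHAM (SD, n = 9 each).

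Among cytokine and chemokine genes 4 of 12 rose and 8 did not pass, and 7 rose adjusted over the list alone. Ccl12 (ENSMUSG00000035352), a monocyte attractant, was at 2.77 ± 2.40 CPM in MM and 0.609 ± 0.361 CPM in SHAM (SD, n = 9 each). Ccl7 (ENSMUSG00000035373) was at 5.51 ± 7.33 CPM in MM and 0.795 ± 0.623 CPM in SHAM (SD, n = 9 each). The list level was 2.52 ± 0.84 in MM and 1.62 ± 0.44 in SHAM (SD, n = 9 each; exact permutation p = 0.0086, adjusted p = 0.0376), and 8 of 9 MM libraries lay above the SHAM median. It no longer passed the exact test without MM1, MM5, MM8, MM9, SHAM1, SHAM2, SHAM3, SHAM5, SHAM7, SHAM8 or SHAM9 (adjusted p = 0.0502, 0.0702, 0.0653, 0.0601, 0.083, 0.0536, 0.0531, 0.0804, 0.0628, 0.084 and 0.0654). It also failed without MM5, MM8 and MM9 (exact adjusted p = 0.266), without SHAM7 and SHAM8 (adjusted p = 0.135), with a replicate block (adjusted p = 0.186) and with medians over members (adjusted p = 0.148). It was highest in MM5 (4.07), MM9 (3.46) and MM8 (3.03), against at most 2.47 in the other MM libraries. With camera the list had adjusted p = 1.66e-05, and adjusted p = 0.344 with an estimated correlation. Of 16 complement and acute phase genes, 0 passed edgeR's test and 4 rose adjusted over the list alone. An unadjusted p under 0.05 was found for 7, all higher in MM, and DESeq2 called 4. That list had a camera adjusted p = 0.00233 upward (adjusted p = 0.382 with an estimated correlation; adjusted p = 0.704 without MM5, MM8 and MM9), and its level did not pass (exact permutation p = 0.125, adjusted p = 0.258). The level stood at 6.39 in MM5, 5.93 in MM9 and 5.40 in MM8, against at most 5.06 in the other MM libraries.

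Erythroid genes fell in 6 of 7 measured members, as they did adjusted over the list alone. Their level was 3.13 ± 0.59 in MM and 5.31 ± 0.98 in SHAM (SD, n = 9 each; exact permutation p = 8.23e-05, adjusted p = 0.00288), and 0 of 9 MM libraries lay above the SHAM median. The list was called by camera (adjusted p = 2.21e-15; adjusted p = 0.12 with an estimated correlation) and by fry (adjusted p = 0.0181). Globin pairs share sequence, so the 4 globin genes are not separate measurements. Hba-a2 (ENSMUSG00000069917) was at 34.3 ± 17.4 CPM in MM and 231.6 ± 231.7 CPM in SHAM (SD, n = 9 each). Hbb-bs (ENSMUSG00000052305), a beta globin, was at 47.3 ± 28.8 CPM in MM and 318 ± 328 CPM in SHAM (SD, n = 9 each). Hbb-bt (ENSMUSG00000073940) was at 7.59 ± 4.54 CPM in MM and 61.1 ± 61.5 CPM in SHAM (SD, n = 9 each). Alas2 (ENSMUSG00000025270), the erythroid enzyme that starts haem synthesis, was at 1.91 ± 0.969 CPM in MM and 12.5 ± 12.5 CPM in SHAM (SD, n = 9 each). Slc4a1 (ENSMUSG00000006574), the red cell anion exchanger, was at 0.988 ± 0.658 CPM in MM and 7.02 ± 6.46 CPM in SHAM (SD, n = 9 each). Hba-a1 reached 752 CPM in SHAM6 and at most 259 CPM in the other SHAM libraries. Of 14 neutrophil and bone marrow genes, 0 passed edgeR's test or did so adjusted over the list alone. An unadjusted p under 0.05 was found for 4, all lower in MM, and DESeq2 called 2 lower. Their level was 1.69 ± 0.79 in MM and 2.01 ± 1.08 in SHAM (SD, n = 9 each; exact permutation p = 0.475). Camera gave adjusted p = 0.0577 downward (adjusted p = 0.665 with an estimated correlation), passing without MM3, MM5, MM9, SHAM1, SHAM2, SHAM3, SHAM8 or SHAM9 (adjusted p = 0.0415, 0.00282, 0.0136, 0.00451, 0.00259, 0.0336, 0.0462 and 0.0116), without MM5, MM8 and MM9 (adjusted p = 0.000755) or with a replicate block (adjusted p = 0.0193).

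**Figure D2:**
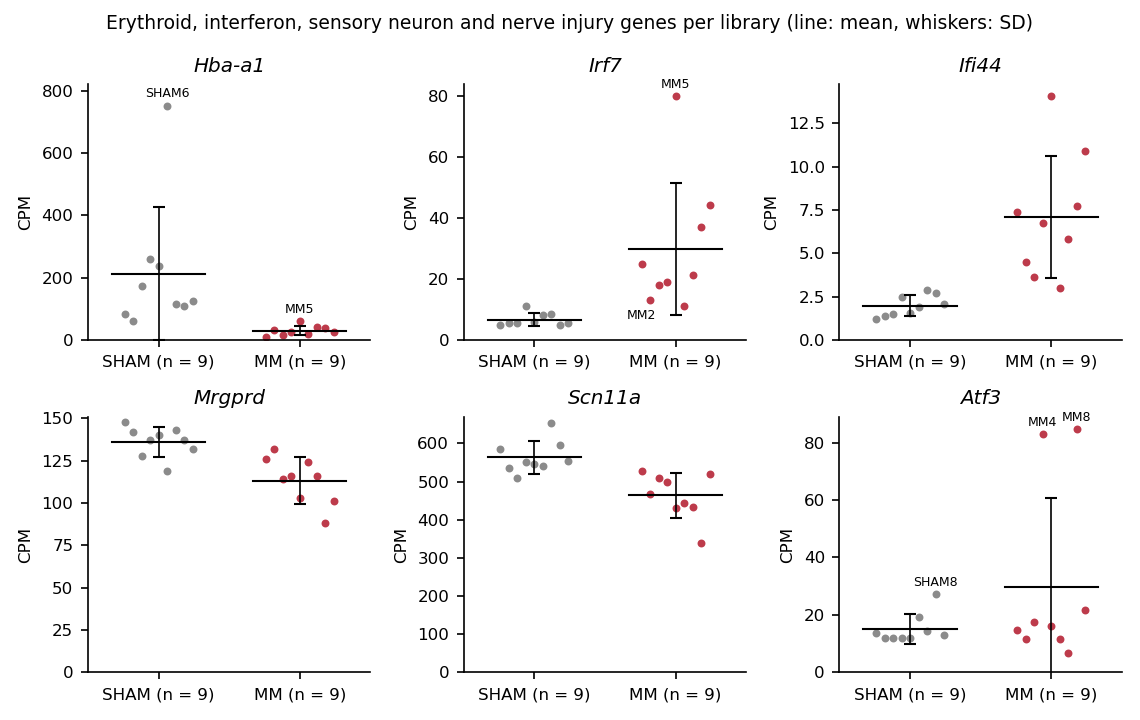
CPM of Hba-a1, Irf7, Ifi44, Mrgprd, Scn11a and Atf3 in each library, 1 point per library, with lines at group means and whiskers of 1 SD that stop at 0 (n = 9 each). Hba-a1 was at or under 60.3 CPM in every MM library and at or above 60.7 CPM in every SHAM library, while Atf3 stood at 83.0 CPM in MM4 and 84.7 CPM in MM8.

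Among 16 markers of non-peptidergic and itch neurons, 2 fell and 14 did not pass, and 4 fell adjusted over the list alone. The 2 past the threshold over all genes were Mrgprd, given above, and Scn11a (ENSMUSG00000034115), which encodes a sodium channel of nociceptors. Scn11a was at 464 ± 59.6 CPM in MM and 563 ± 42.8 CPM in SHAM (SD, n = 9 each; log2 fold change -0.28 ± 0.07 SE). With scaling by total counts alone neither passed with edgeR (adjusted p = 0.0515 for Mrgprd and adjusted p = 0.0521 for Scn11a). With 1 library left out the call was lost in 11 of 18 fits for Mrgprd and in 13 of 18 for Scn11a. Camera called the list lower (adjusted p = 4.37e-05; adjusted p = 0.308 with an estimated correlation). Its level, 5.20 ± 0.17 in MM and 5.37 ± 0.10 in SHAM, did not pass after correction (SD, n = 9 each; exact permutation p = 0.0165, adjusted p = 0.0641), but did without MM1, MM4 or SHAM3 (adjusted p = 0.0317, 0.0336 and 0.044). Of 12 peptidergic nociceptor genes, 0 passed edgeR's test or did so adjusted over the list alone. Among them 2 had an unadjusted p under 0.05 with lower values, and DESeq2 called 0. Calca (ENSMUSG00000030669), the precursor of the pain neuropeptide CGRP, was at 810 ± 102 CPM in MM and 794 ± 95.3 CPM in SHAM (SD, n = 9 each), with adjusted p = 0.866 from edgeR. The list's camera test gave adjusted p = 0.311 (adjusted p = 0.707 with an estimated correlation).

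All 16 markers of A-fibre and touch neurons had negative fold changes, with a median log2 fold change of -0.22. None passed edgeR's test or did so adjusted over the list alone, 7 had an unadjusted p under 0.05, and DESeq2 called 0. Camera called them lower with adjusted p = 2.26e-05 (adjusted p = 0.361 with an estimated correlation; adjusted p = 0.0414 without MM5, MM8 and MM9). Their level was lowest in MM5 (6.31), MM9 (6.89) and MM8 (7.15), against 7.22 to 7.54 in the other MM libraries. The level test gave exact permutation p = 0.0598 and adjusted p = 0.15, or adjusted p = 0.0346 without SHAM6. Of 26 genes for ion channels linked to pain, 25 had negative fold changes with a median of -0.20. None passed edgeR's test, 9 had an unadjusted p under 0.05, DESeq2 called 1 lower, and 1 fell adjusted over the list alone. Camera called the channel genes lower with adjusted p = 3.27e-06 (adjusted p = 0.361 with an estimated correlation; adjusted p = 0.0178 without MM5, MM8 and MM9). Their level was 5.72 in MM5 and 6.16 in both MM8 and MM9, against 6.35 to 6.52 in the other MM libraries. The level test gave exact permutation p = 0.0289 and adjusted p = 0.0919, and passed without MM3 or SHAM6 (adjusted p = 0.0476 and 0.0143). Genes for analgesic and inhibitory receptors had a median log2 fold change of -0.14 over 17 members. None passed edgeR's test or did so adjusted over the list alone, 4 had an unadjusted p under 0.05 with lower values, and DESeq2 called 0. For these genes camera gave adjusted p = 0.00994 (adjusted p = 0.361 with an estimated correlation; adjusted p = 0.493 without MM5, MM8 and MM9), and the level was 4.46, 4.81 and 4.75 in these 3 against 4.97 to 5.06 in the other MM libraries.

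Among 19 genes of nerve injury and regeneration, 1 rose and 18 did not pass, 2 rose adjusted over the list alone, and all 19 fold changes were positive. The 1 that rose was Tubb6 (ENSMUSG00000001473), a beta tubulin, at 34.4 ± 10.6 CPM in MM and 23.5 ± 1.86 CPM in SHAM (SD, n = 9 each). Atf3 (ENSMUSG00000026628), a transcription factor induced by axon damage, was at 29.8 ± 30.9 CPM in MM and 15.1 ± 5.11 CPM in SHAM (SD, n = 9 each), and did not pass (edgeR adjusted p = 0.200). The list had a camera adjusted p = 0.00247 (adjusted p = 0.551 with an estimated correlation), and no longer passed without MM4 or MM8 (adjusted p = 0.102 and 0.0575). The list level was 5.34 in MM4 and 5.44 in MM8, and between 2.96 and 4.08 in the other MM libraries. The difference between groups gave exact permutation p = 0.411. Among 31 axon guidance genes 1 rose and 30 did not pass, while adjusted over the list alone 1 rose and 1 fell. The ephrin receptor gene Epha7 (ENSMUSG00000028289) was at 19.3 ± 17.6 CPM in MM and 5.80 ± 0.915 CPM in SHAM (SD, n = 9 each). This list had a median log2 fold change of -0.09 against its mean of 0.00. Camera called it lower (adjusted p = 0.0239; adjusted p = 0.308 with an estimated correlation). The call was lost without MM3, without MM9 and without MM5, MM8 and MM9 (adjusted p = 0.051, 0.0684 and 0.19), and the list turned upward with the immunoglobulin level as a covariate (adjusted p = 0.21). Neurotrophin and growth factor genes had 0 of 14 members past edgeR's test, 3 with an unadjusted p under 0.05 and higher values, 1 called by DESeq2 and 1 that rose adjusted over the list alone. Camera gave them adjusted p = 0.171 (adjusted p = 0.382 with an estimated correlation). Their level gave exact permutation p = 0.0641 and adjusted p = 0.15, or adjusted p = 0.0308 without MM3.

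**Figure D3:**
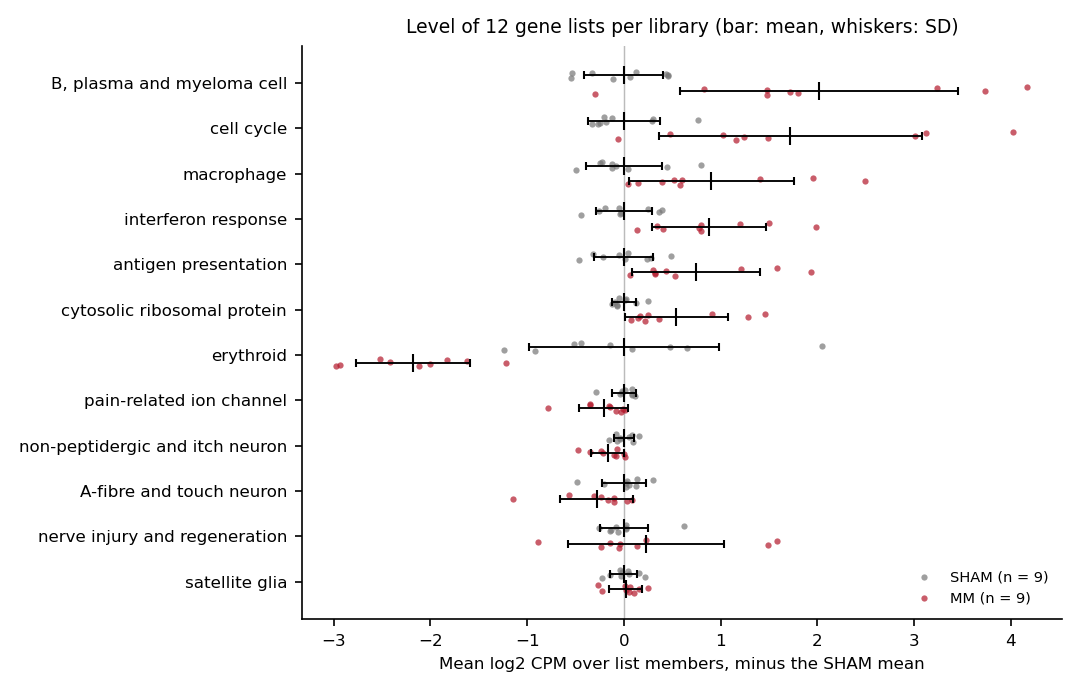
Level of 12 gene lists in each library, as mean log2 CPM over members minus the SHAM mean, with MM and SHAM side by side, 1 point per library, bars at group means and whiskers of 1 SD (n = 9 each). The difference between MM and SHAM means was 2.02 for B, plasma and myeloma cell genes, 1.72 for cell cycle genes, 0.88 for interferon response genes and -2.18 for erythroid genes.

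Of 15 satellite glia genes, 0 passed edgeR's test, did so adjusted over the list alone, had an unadjusted p under 0.05 or were called by DESeq2. Their level was 6.41 ± 0.17 in MM and 6.39 ± 0.14 in SHAM (SD, n = 9 each; exact permutation p = 0.808). The camera test gave adjusted p = 0.34, and adjusted p = 0.67 with an estimated correlation. The median log2 fold change of that list was -0.03 and its mean 0.03. Myelinating Schwann cell genes had 16 of 16 positive fold changes with a median of 0.21. None passed edgeR's test or did so adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 1 called by DESeq2. Camera gave them adjusted p = 0.12 (adjusted p = 0.707 with an estimated correlation), and passed without MM3, MM9, SHAM4 or SHAM6 (adjusted p = 0.012, 0.0136, 0.0246 and 0.017). Among 11 genes of non-myelinating and repair Schwann cells, 1 fell, also adjusted over the list alone: the adhesion molecule gene Ncam1 (ENSMUSG00000039542), at 99.5 ± 11.4 CPM in MM and 116 ± 4.71 CPM in SHAM (SD, n = 9 each). The other 10 did not pass, and camera gave adjusted p = 0.0596 (adjusted p = 0.361 with an estimated correlation), passing without MM3, MM9, SHAM6 or SHAM8 (adjusted p = 0.0383, 0.0345, 0.0329 and 0.0462) and without SHAM7 and SHAM8 (adjusted p = 0.0467). Of the T and NK cell list, 3 members were measured, 0 passed edgeR's test or did so adjusted over the list alone, 2 had an unadjusted p under 0.05 with higher values and DESeq2 called 0. The list was too small for a list test.

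All 14 endothelial genes had positive fold changes with a median of 0.31. None passed edgeR's test or did so adjusted over the list alone, 3 had an unadjusted p under 0.05, and DESeq2 called 0. Their camera test gave adjusted p = 0.0103 (adjusted p = 0.551 with an estimated correlation), lost without MM5 or MM7 (adjusted p = 0.0924 and 0.0629), without MM5, MM8 and MM9 (adjusted p = 0.527) and with the immunoglobulin level as a covariate (adjusted p = 0.954). Mural cell genes had a median of -0.14 over 11 members, 0 past edgeR's test or adjusted over the list alone, 3 with an unadjusted p under 0.05 and lower values, and 0 called by DESeq2. Camera gave them adjusted p = 0.131 (adjusted p = 0.58 with an estimated correlation; adjusted p = 0.00834 without MM5; adjusted p = 0.0023 without MM5, MM8 and MM9). Among 22 fibroblast and extracellular matrix genes 1 rose, also adjusted over the list alone: Timp1 (ENSMUSG00000001131), a metalloproteinase inhibitor, at 12.7 ± 13.3 CPM in MM and 2.02 ± 0.998 CPM in SHAM (SD, n = 9 each). The other 21 did not pass, and camera gave adjusted p = 0.1 (adjusted p = 0.707 with an estimated correlation), passing without MM3, MM4, SHAM4 or SHAM6 (adjusted p = 0.00764, 0.0306, 0.0209 and 0.0034). Their level was highest in MM5 (7.16), MM8 (6.12) and MM9 (6.06), against at most 5.79 in the other MM libraries.

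Markers of tissue next to the ganglion varied between libraries. Acta1, skeletal muscle actin, reached 5250 CPM in SHAM8, 1040 CPM in SHAM7 and 544 CPM in MM6, and at most 316 CPM elsewhere. The 15 skeletal muscle genes had a median log2 fold change of -2.62 while their level differed by 0.08 in the other direction (exact permutation p = 0.958). None passed edgeR's test or did so adjusted over the list alone, 4 had an unadjusted p under 0.05 with lower values and DESeq2 called 0. The camera test gave adjusted p = 0.151 downward (adjusted p = 0.71 with an estimated correlation), and passed downward without MM6, SHAM1, SHAM3 or SHAM9 (adjusted p = 0.043, 0.0317, 0.0402 and 0.0345). It passed upward without SHAM7 and SHAM8 (camera adjusted p = 0.0108) and with the skeletal muscle level as a covariate (adjusted p = 0.034), so the list had no stable direction. For adipocyte genes 0 of 5 passed edgeR's test or did so adjusted over the list alone, 1 had an unadjusted p under 0.05 with a lower value and DESeq2 called 0. Their camera result was adjusted p = 0.151 (adjusted p = 0.602 with an estimated correlation; adjusted p = 0.00358 without MM5 and adjusted p = 0.0345 without MM9; adjusted p = 3.96e-06 without MM5, MM8 and MM9). Central nervous system genes had 0 of 5 past edgeR's test, adjusted over the list alone, with an unadjusted p under 0.05 or called by DESeq2 (camera adjusted p = 0.243; adjusted p = 0.58 with an estimated correlation). The lumbar Hox list, which marks body level, had 11 of 11 negative fold changes with a median of -0.10, and 0 past edgeR's test, adjusted over the list alone, with an unadjusted p under 0.05 or called by DESeq2. Camera gave it adjusted p = 0.0248 (adjusted p = 0.515 with an estimated correlation), lost without MM5 or MM9 (adjusted p = 0.054 and 0.15), and turned upward without MM5, MM8 and MM9 (adjusted p = 0.886).

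Among 16 immediate early genes 1 rose and 15 did not pass, and 6 rose adjusted over the list alone. Btg2 (ENSMUSG00000020423), an antiproliferative early gene, was at 28.0 ± 26.2 CPM in MM and 8.64 ± 4.26 CPM in SHAM (SD, n = 9 each). Camera gave the list adjusted p = 7.81e-05 (adjusted p = 0.361 with an estimated correlation; adjusted p = 0.041 without MM5, MM8 and MM9). Its level was highest in MM9 (4.93), MM5 (4.86) and MM8 (4.63), against at most 4.02 in the other MM libraries; it gave exact permutation p = 0.0492 and adjusted p = 0.132, or adjusted p = 0.0143 without SHAM6. Glucocorticoid response genes included 1 that rose of 16, with 15 not passing and 2 rising adjusted over the list alone. It was Nfkbia (ENSMUSG00000021025), the NF-kappaB inhibitor, at 36.5 ± 12.5 CPM in MM and 20.5 ± 6.71 CPM in SHAM (SD, n = 9 each). For this list camera gave adjusted p = 0.00285 (adjusted p = 0.361 with an estimated correlation). Circadian clock genes had 0 of 16 past edgeR's test or adjusted over the list alone, 1 with an unadjusted p under 0.05 and a lower value, and 0 called by DESeq2 (camera adjusted p = 0.16; adjusted p = 0.494 with an estimated correlation; adjusted p = 0.047 without MM5, MM8 and MM9). Neither the 13 mitochondrially encoded genes nor the 25 nuclear oxidative phosphorylation genes had a member past edgeR's test, adjusted over the list alone, with an unadjusted p under 0.05 or called by DESeq2. The mitochondrially encoded list had a median log2 fold change of -0.01 and a level difference of 0.02 (camera adjusted p = 0.649; adjusted p = 0.87 with an estimated correlation). The nuclear list had a median of 0.02 (camera adjusted p = 0.385; adjusted p = 0.807 with an estimated correlation; adjusted p = 0.0462 without SHAM8; adjusted p = 0.0262 without SHAM7 and SHAM8). The cholesterol synthesis list had 0 of 18 past edgeR's test or adjusted over the list alone, 2 with an unadjusted p under 0.05 and higher values, and 0 called by DESeq2. Its camera result was adjusted p = 0.0728 (adjusted p = 0.641 with an estimated correlation; adjusted p = 0.000783 without MM9 and adjusted p = 0.0173 without SHAM6; adjusted p = 0.000477 without MM5, MM8 and MM9). Outside the lists, the long non-coding RNA Snhg11 (ENSMUSG00000044349) fell, at 2.94 ± 1.0 CPM in MM and 6.67 ± 3.96 CPM in SHAM (SD, n = 9 each).

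The test of single genes was edgeR's quasi-likelihood test with a Benjamini-Hochberg threshold of 0.05; 3556 genes had an unadjusted p under 0.05, and 23 genes (0.15%, against 0.00411% by chance) had no overlap between the groups. The first principal component held 39.9% of the variance and set MM5, MM9 and MM8 apart at -87.5, -73.2 and -47.6; without these 3 libraries 53 genes rose and 7 fell, and 57 of the 471 were among them. Without them the difference in level between groups moved from 2.02 to 1.17 for B, plasma and myeloma cell genes, from 1.72 to 0.89 for cell cycle genes and from 0.88 to 0.54 for interferon response genes. Without SHAM7 and SHAM8, the libraries highest in skeletal muscle genes, 29 rose and 6 fell. With the immunoglobulin level as a covariate 0 passed, where 1399 had an unadjusted p under 0.05 and 320 of the 471 changed sign. That level itself differed between the groups, so this fit cannot separate group from immunoglobulin level. Under that covariate 15 of the 20 lists that camera had called changed direction. The calls of non-peptidergic neuron, endothelial and glucocorticoid response genes were lost (adjusted p = 0.129, 0.954 and 0.0556), and those of erythroid and interferon response genes stayed (adjusted p = 8.43e-09 and 0.0386). With the level of neuron genes as a covariate 13 genes rose and 12 fell, and 21 of the 471 were among them.

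The number of genes past the threshold depended on the tool and moved with 1 library left out: limma-voom called 0 (3149 with an unadjusted p under 0.05) and DESeq2 1376 (1133 higher and 243 lower). Leaving out 1 library gave 760 without MM1, 1014 without MM2, 84 without MM5, 104 without MM8, 121 without MM9, 120 without SHAM1, 137 without SHAM2, 131 without SHAM3, 287 without SHAM4, 183 without SHAM5, 732 without SHAM6, 125 without SHAM7, 122 without SHAM8 and 153 without SHAM9. Of the 38 named genes that passed, Igkc, Ighg2b, Ighv1-54, Igkv10-96, Il5ra, Lax1, Irf4, Pou2af1, Ccnb1, Cdk1, Ifi44, Irf7, Hbb-bt, Hbb-bs, Hba-a1, Hba-a2, Alas2, Slc4a1, Ctss and Cd68 passed in all 18 of these fits. The other 18 lost the call in some: 1 gene without MM3 or SHAM6, 2 without MM4, 4 without MM6, 6 without MM7, 13 without SHAM4, 14 without SHAM9, 15 without MM9 or SHAM3, 16 without MM5, SHAM2 or SHAM5, and 17 without MM8, SHAM1, SHAM7 or SHAM8. Camera with the preset correlation called 13 lists higher and 7 lower, against 0 lists with an estimated correlation and 2 with fry, and 44 of 100 splits of the libraries gave as many lists. By list level 7 lists were higher and 1 was lower, and the levels not printed above had an exact permutation adjusted p of at least 0.132.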

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

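The rule behind these values was fixed before the data were examined, no explanation was tested for any of them, and no test here was chosen after the result was seen. In each measure within MM or SHAM, the highest or lowest library was set against the other 8 by the gap to its nearest neighbour relative to the whole range. Of 160 such groups of libraries 16 held a library that stood apart, where chance gives about 8.

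Library MM5 was low in neuron measures: its peptidergic nociceptor level was 5.07, against 5.55 to 6.01 in the other MM libraries. Its level of pain-related ion channel genes was 5.72, against 6.16 to 6.52. Calca stood at 9.19 log2 CPM in MM5, against 9.64 to 9.88, and Cd79a, the B cell receptor chain, was high at 1.95 log2 CPM, against 0.77 to 1.27. In MM8, Scn11a was low at 8.41 log2 CPM, against 8.75 to 9.05 in the other MM libraries.

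Library SHAM6 stood apart from the other SHAM libraries in 6 measures. Its immediate early level was 4.76 (others 3.15 to 3.62), with Btg2 at 4.32 log2 CPM (others 2.70 to 3.17). Ccl7 was at 1.32 log2 CPM (others -1.12 to -0.11) and Rps27a at 6.15 log2 CPM (others 5.63 to 5.89). Its cholesterol synthesis level was 7.27 (others 7.04 to 7.12), and its level of pain-related ion channel genes was low at 6.22 (others 6.47 to 6.62).

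Library SHAM8 was high in 5 measures. Its nerve injury level was 4.47 (others 3.60 to 3.87), its adipocyte level 5.28 (others 0.26 to 2.59) and its nuclear oxidative phosphorylation level 6.24 (others 5.90 to 6.04). Immunoglobulin constant-region genes summed to 121.8 CPM in SHAM8 (others 41.64 to 80.59), with Ighm at 111 CPM and Ighg2b at 0.477 CPM. The 20 most abundant genes held 11.41% of its reads (others 8.46% to 9.27%).

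Among 319 transcripts that have no gene in the annotation used, and so stand outside the gene comparison, 1 passed the threshold. Transcript ENSMUST00000238813 was at 8.43 ± 9.26 CPM in MM and 0.19 ± 0.23 CPM in SHAM (SD, n = 9 each; log2 fold change 5.40), and its highest value was 27.06 CPM in MM9. Of 37 deposited genes without a match, 0 passed with limma.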

How the results depend on the processing

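Fits without MM5, MM8 and MM9, fits without SHAM7 and SHAM8, and the skeletal muscle and immunoglobulin covariates were chosen only after the results were seen; the other alternatives were planned. The 471 genes became 1376 with DESeq2, 0 with limma-voom (3149 at an unadjusted p under 0.05), 48 with limma-voom and library weights, 219, 207 and 248 with limma on deposited values (pseudocount 1, pseudocount 0.1, no filter), 25 (13 higher and 12 lower) with the neuron level as a covariate and 0 with the immunoglobulin level as a covariate (1399 at an unadjusted p under 0.05). Without MM5, MM8 and MM9 there were 60 genes, without SHAM7 and SHAM8 35, and with 1 library left out between 84 and 1014. With a replicate block there were 8; libraries of the same number had correlations between -0.32 and 0.26 after removal of group means, so the numbers were not read as pairs. RLE scaling, total counts, no filter, a mean of at least 1 CPM, the length offset, surrogate variables and the skeletal muscle covariate kept the count within 1.5 times of 471. The genes themselves were not all the same. Of the 471, 438 still passed with RLE scaling, 447 with total counts, 464 with a mean of at least 1 CPM and 413 with the length offset. Fewer still passed with no filter (214), surrogate variables (294) and the skeletal muscle covariate (331). Camera called 20 lists, 0 with an estimated correlation, 2 with fry and between 16 and 24 in every other fit. List levels called 8 lists, 5 with medians over members, 3 with a replicate block, 4 without MM5, MM8 and MM9, 4 without SHAM7 and SHAM8, and between 5 and 11 with 1 library left out. The immunoglobulin transcript share, a difference of 2117.9 CPM, was 2125.9 CPM without SHAM7 and SHAM8. The exact permutation p there rose to 0.0517 with groups of unequal size, and does not show that the difference rests on those libraries. The share kept its side of the threshold in the other fits, between 1411.2 and 2382.1 CPM with 1 library left out. The same held at 447.5 CPM without MM5, MM8 and MM9. Fewer libraries were tested in the fits that left some out; the cause of the other changes was not tested.

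With the immunoglobulin level as a covariate, which itself differed between the groups, 18 lists changed direction in camera, 15 of them among the 20 called. They turned upward for peptidergic nociceptor (adjusted p = 0.179), A-fibre and touch neuron (adjusted p = 0.071), pain-related ion channel (adjusted p = 0.0571), analgesic and inhibitory receptor (adjusted p = 0.0386), axon guidance (adjusted p = 0.21), satellite glia (adjusted p = 0.0266) and lumbar Hox genes (adjusted p = 0.000354). They turned downward for nerve injury (adjusted p = 0.104), macrophage (adjusted p = 0.136), B, plasma and myeloma cell (adjusted p = 0.0162), antigen presentation (adjusted p = 0.0457), cytokine and chemokine (adjusted p = 0.672), complement (adjusted p = 0.0277), fibroblast and extracellular matrix (adjusted p = 0.0386), immediate early (adjusted p = 0.21), cell cycle (adjusted p = 3.82e-06), unfolded protein response (adjusted p = 0.000176) and ribosomal protein genes (adjusted p = 9.01e-07). Calls were lost without a change of direction for non-peptidergic and itch neuron (adjusted p = 0.129), endothelial (adjusted p = 0.954) and glucocorticoid response genes (adjusted p = 0.0556). Calls were gained upward for myelinating Schwann cell (adjusted p = 0.00354) and cholesterol synthesis (adjusted p = 0.000127), and downward for neutrophil and bone marrow (adjusted p = 0.000225) and adipocyte genes (adjusted p = 2.2e-05). In the same fit 320 of the 471 genes changed sign. Of the 38 named genes that passed, 27 lost the call there and 11 changed sign, at log2 fold changes of -0.389 for Cdk1, -0.391 for Ctss, -0.668 for Cd68, -0.482 for H2-K1, -0.178 for Epha7, -0.41 for Psmb9, -0.288 for Ccl7, -0.223 for Rps27a, -0.277 for Rpl18, -0.707 for Btg2 and -0.444 for Pdia4. Atf3 (-0.406) and Ddx3y (0.044), which had not passed, changed sign as well.

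Without MM5, MM8 and MM9, camera turned upward for lumbar Hox (adjusted p = 0.886), peptidergic nociceptor (adjusted p = 0.716) and satellite glia (adjusted p = 0.807), and downward for fibroblast genes (adjusted p = 0.0579). The level difference changed sign there for peptidergic nociceptor (0.042), fibroblast and extracellular matrix (-0.136) and mitochondrially encoded genes (-0.02). Skeletal muscle turned upward in camera without SHAM7 and SHAM8 (adjusted p = 0.0108), with its own level as a covariate (adjusted p = 0.034), with a replicate block (adjusted p = 0.612) and without SHAM8, the highest adjusted p (0.71) with 1 library left out; the lowest was 0.0317. Mitochondrially encoded genes turned upward in camera without SHAM7 and SHAM8 (adjusted p = 0.156) and without MM4, SHAM7 or SHAM8 (adjusted p = 0.261 to 0.954 over all fits with 1 library left out), and nuclear oxidative phosphorylation genes downward without MM3 (adjusted p = 0.958; lowest 0.0462 with 1 library left out). With medians over members the level difference changed sign for axon guidance (0.016), satellite glia (-0.142), non-myelinating and repair Schwann cell (0.07) and mitochondrially encoded genes (-0.092). With 1 library left out the level difference ran from -0.083 to 0.034 for peptidergic nociceptor, -0.012 to 0.054 for satellite glia, -0.435 to 0.924 for skeletal muscle and -0.03 to 0.08 for mitochondrially encoded genes, and the log2 fold change of Calca from -0.002 to 0.077.

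Over all single lists and alternatives, camera results changed direction 31 times, 16 of them for called lists, and otherwise gained a call 42 times and lost it 53 times. Levels changed direction 25 times, never for a called list or past the threshold, and otherwise gained a call 11 times and lost it 38 times. Named genes changed direction 14 times and otherwise lost a call 454 times. All other results of single lists and genes kept their direction and side of the threshold. At this depth, with 9 libraries per group and the spread of SHAM libraries alone, simulated changes of 1.5-fold were recovered for 84% of genes. Real recovery may be lower, so a gene that did not pass may still differ by that much.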

Other observations

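The count of genes over splits was planned; the count of camera lists over splits and all other tests below were chosen only after the result was seen. Genes of nerve injury and regeneration stood high in a pair of MM libraries, MM4 and MM8. Atf3 was at 83.0 CPM in MM4 and 84.7 CPM in MM8, against 6.80 to 21.8 CPM in the other MM libraries, and 27.3 CPM in SHAM8, the highest SHAM library. Sprr1a, a small proline-rich protein of regenerating axons, was at 88.7 CPM in MM4 and 153 CPM in MM8, against at most 13.1 CPM in the other MM libraries and 37.5 CPM in SHAM8. The neuropeptide Gal was at 44.0 and 69.0 CPM in MM4 and MM8, against at most 20.3 CPM in the other MM libraries and 16.2 CPM in SHAM. Npy was at 15.7 and 20.2 CPM, against at most 5.15 CPM in the other MM libraries and 9.39 CPM in SHAM8. Ecel1, an endopeptidase of injured neurons, was at 14.7 and 26.1 CPM, against at most 4.15 CPM in the other MM libraries and 9.65 CPM in SHAM8. Sox11, a transcription factor of growing axons, was at 19.9 and 19.5 CPM, against at most 8.88 CPM in the other MM libraries and 12.4 CPM in SHAM8. In SHAM, SHAM8 was highest for Npy, Ecel1 and Sox11. Csf1, which recruits microglia and macrophages, was at 46.3 CPM in MM4, 44.7 CPM in MM5 and 39.5 CPM in MM8, against at most 31.6 CPM in the other MM libraries and 25 CPM in SHAM.

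Other rising genes also differed in how closely they followed Ighg2b over the 8 MM libraries with more Ighg2b than any SHAM library. For each gene the CPM above the SHAM mean was divided by Ighg2b, and the highest ratio by the lowest. That value was 1.35 for Igkc, 1.64 for Ccnb1, 1.92 for Irf4, 2.15 for H2-K1, 2.32 for Btg2, 2.71 for Pdia4 and 3.59 for Epha7. It was 30.0 for Tubb6, 54.3 for Jchain and 85.8 for Nfkbia.

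Real groups gave 471 genes, and 1 of 100 splits, the real one, gave as many, while the highest other split gave 1 gene. Chance is thus argued against for the count. As 100 of 24310 splits were drawn, no share under 1 in 100 could be shown. For lists called by camera at the preset correlation, 44 of 100 splits gave as many as the real 20 and the highest other gave 26, so chance cannot be excluded for that count.

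In MM 10 of 16 B, plasma and myeloma cell genes and 15 of 18 cell cycle genes rose. Host plasma cells of many clones are argued against, since Ighv1-54 held a median 99.1% of heavy chain variable reads in MM. Normal bone marrow carried over at dissection is argued against too: the neutrophil and bone marrow level differed by -0.33 (at most 0.57 with 2 standard errors added), while the B, plasma and myeloma cell level differed by 2.02 (at least 1.02). RNA of 1 clone of inoculated myeloma cells in the samples is a candidate explanation: the median range of the ratio to Ighg2b was 3.64 over 24 rising genes of these lists, against 7.53 over all 432 rising genes, of which 156 had at most 5. Whether such cells lay in the ganglion, in its vessels or in tissue taken with it, marrow replaced by tumour included, stays open.

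Libraries SHAM5 and SHAM9 held transcripts of the same variable segments as MM, with 14.8 and 16.4 CPM of Ighg2b and ratios of Igkc to Ighg2b of 1.01 and 0.902, within the MM range of 0.744 to 1.01. A swap of either with MM2 is argued against by the erythroid level. It was 3.20 in MM2, under the lowest of the other SHAM libraries (4.07), while SHAM5 (5.79) and SHAM9 (4.87) lay above the highest of the other MM libraries (4.10). Some other levels of MM2 lay within the SHAM range, as for interferon response (3.47, SHAM 2.89 to 3.73) and cell cycle genes (0.77, SHAM 0.50 to 1.60). For interferon response, SHAM5 (3.08) and SHAM9 (3.28) lay under the lowest of the other MM libraries (3.67). Reads or RNA carried over from MM samples cannot be told apart from myeloma cells in these mice, as Ighg2b amounted to 0.374% of the highest MM library in SHAM9 and 0.337% in SHAM5, and the labels give no handling or sequencing order. Myeloma cells in vehicle-treated mice were not tested.

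In MM 16 of 25 interferon response genes rose. The ratio to Ighg2b ranged a median 22.2-fold over 16 rising members (lower quartile 18.2), with Stat2 not defined and ranked as the largest. These values go against RNA of the inoculated myeloma cells as the source of the whole rise, but lean on MM7. That library had the least Ighg2b of the 8 (104 CPM) and the highest ratio of Irf7 and of Ifi44. Ranges without MM7 were not taken, so this source is not settled. For a lower share of neurons as the source of the whole rise, only satellite glia were tested. Their level differed by 0.02 (at most 0.16 with 2 standard errors added) and the interferon response level by 0.88 (at least 0.44). Other levels differed by 0.21 for myelinating Schwann cell, 0.24 for endothelial and 0.25 for fibroblast and extracellular matrix genes. They differed by -0.06 for non-myelinating and repair Schwann cell and -0.23 for mural cell genes. With the level of neuron genes as a covariate 21 of the 471 genes still passed. That count covers all genes, and the interferon response list was not tested in that fit. A lower share of neurons as part of the rise stays open, and for the whole rise it is not settled. A response of host cells to the inoculated tumour may be a candidate explanation, which the design cannot separate from interferon-responsive cells entering the ganglion. A part of the rise from myeloma RNA also stays open, as the level was highest in MM5, MM9 and MM8.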
